A study of Rattus norvegicus with 129 samples.

How the data were processed

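Gene expression was measured in 129 rat liver samples on 3 types of one-colour array, in 31 groups of 5 studies. The deposited values are intensity per probe set on a linear scale, with negative values, and the upstream steps that made them are not given in the sources used here. Between arrays of a study the medians of log2 values ranged over 1.34 in the phenobarbital and PCN study, 1.73 in the D3T study, 0.28 in the 3-week PFOS study, 1.05 in the PFOA and PFOS study and 0.96 in the Wy-14643 study. The share of values at or under 0 per array was 21.0 to 25.5 percent, 27.9 to 32.6 percent, 25.7 to 26.9 percent, 17.6 to 20.7 percent and 15.2 to 17.4 percent in the same order. Groups were taken from the sample labels, which give each rat a number.

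Studies whose array medians lay within 0.5 of each other were used as deposited, and the arrays of the others were quantile normalised within the study, so that the 3-week PFOS study alone was left as it was. Negative values were set to 0 and log2(value + 16) was taken, which puts a floor at 4.00. Control probe sets were left out of the tests. The array of the phenobarbital, D3T and 3-week studies had 8799 probe sets, of which 8740 were tested. Of all 7018 carried 1 gene symbol, 308 several and 1473 none, for 4737 genes. The array of the PFOA and PFOS study had 31099 with 31042 tested, and 20832, 436 and 9831 in these classes for 14218 genes. That of the Wy-14643 study had 15923 with 15866 tested, and 12789, 312 and 2822 for 10412 genes. Cyp2b1 was present on shared probe sets alone and was not analysed here.

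Each study was fitted with limma 3.58.1 in R 4.3.3 (lmFit with group means, then eBayes), and p was adjusted by Benjamini-Hochberg over all tested probe sets of the array. A probe set counted as changed where the adjusted p was under 0.05. All p-values are two-sided. There were 26 comparisons: each treatment against its vehicle at each time and sex, phenobarbital minus PCN at 5 days, PFOA minus PFOS, vehicle females minus males, and 3 interactions, the phenobarbital and PCN effects in females minus those in males and the Wy-14643 effect at 7 days minus that at 1 day. A gene was read from its probe set with the highest mean. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

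The groups compared, the tests, the alternatives, the key genes and 30 gene lists were chosen before the data were examined. The lists were phase 1 enzymes under CAR or PXR, conjugation and transport, NRF2, AHR, PPARα, mitochondrial and peroxisomal fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acids, glucose metabolism, urea and amino acids, acute phase, complement and coagulation, cell cycle, p53 damage response, heat shock, ER stress, proteasome, ribosome, clock, nuclear receptors, genes with a male or a female bias, and markers of macrophages, endothelium, stellate cells, bile ducts, lymphocytes and blood. Lists with at least 4 measured members were tested with camera of limma at its preset correlation of 0.01, adjusted over all 780 list tests. Named genes were the key genes, up to 4 members per list with the largest change among those that passed, and the 5 genes with the largest rise and the 5 with the largest fall that passed in each comparison. Genes outside this rule are given as chosen after their values were seen.

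Signatures were the genes changed at least 2-fold by phenobarbital or PCN at 5 days in the sex of the tested study, by Wy-14643 at 7 days or by D3T, matched by symbol and tested with camera in the PFOA, PFOS and 3-week PFOS comparisons. A second, exclusive version left out of the phenobarbital and PCN signatures the genes that Wy-14643 changed at any time, and out of the Wy-14643 signature those that phenobarbital or PCN changed at 5 days in that sex. In all 42 signature tests were run.

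Alternatives were a pseudocount of 1 or 64, median scaling in place of quantile normalisation (or the reverse), the lowest 33.3 percent of probe sets left out, trend and robust moderation, a fit of only the groups compared, each array left out in turn, and a replicate block for D3T. For lists they were an estimated correlation, the rotation test fry, the mean of a gene's probe sets and the other normalization, and for signatures the top 100 genes, an earlier time of the reference and an estimated correlation. Alternatives with the displaced values of vehicle rat 1003 moved back, or without its array for lists, signatures and comparisons that do not hold its group, and a replicate block by the place of the rat number within its group in the phenobarbital and PCN and the 3-week PFOS studies, were chosen after seeing the data. Groups were also split anew, with up to 100 splits per comparison.

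The fit was tested on simulated data with 200 changed probe sets per study. It recovered 159 at the size of the phenobarbital and PCN study (22 of 50 at a log2 change of 0.5, 42 at 1, 45 at 2 and 50 at 3), 132 at that of the D3T study (14, 29, 41 and 48), 145 at that of the Wy-14643 study (10, 36, 49 and 50) and 75 at that of the PFOA and PFOS study (0, 1, 30 and 44). At the size of the 3-week PFOS study it recovered 0 at every size of change. Unchanged probe sets made up 8.62, 8.97, 7.64 and 7.41 percent of calls in the others. Of unchanged lists 0 passed, with correlated genes untested.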

Results

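The data were 129 expression arrays of rat liver RNA from 5 studies, each array from 1 rat. The 90 arrays of the phenobarbital and PCN study covered 18 groups of 5 rats, male and female, given vehicle, phenobarbital or PCN by gavage at 100 mg/kg. Livers were taken 6 or 24 h after 1 dose, or 24 h after the last of 5 daily doses. Phenobarbital is the classic activator of the receptor CAR, and PCN, a synthetic steroid, that of the rat receptor PXR. On the same array type, 8 female rats ate control diet or a diet with D3T at 600 mg/kg (4 each), and 4 female rats received vehicle or the perfluorinated sulfonate PFOS at 5 mg/kg/day for 3 weeks (2 each). A larger array held 9 male rats given vehicle, the perfluorinated carboxylate PFOA at 20 mg/kg/day or PFOS at 10 mg/kg/day (3 each), with a duration that the labels leave out. A further array held 18 male rats on vehicle or the PPARα agonist Wy-14643 at 60 mg/kg/day for 1, 3 or 7 days (3 each), and the label of the Wy-14643 rat 06 states no dose. D3T is an activator of the transcription factor NRF2, which responds to oxidative stress. The series asks whether genes under CAR and PXR respond to perfluoroalkyl acids.

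Deposited mean intensities per array were 159 to 453 in the phenobarbital and PCN study and 92.2 to 416.6 in the D3T study. They were 191 to 294 in the 3-week PFOS, 245 to 383 in the PFOA and PFOS and 314 to 609 in the Wy-14643 study. The number of arrays limits the precision. Changes are log2 differences of group means ± SE from limma, and understate the fold of genes near the floor of 4.00. List members not counted as higher or lower did not pass. Behind each list stand the count adjusted over the list alone, the adjusted p of its test, that with an estimated correlation between genes, and its range over the alternatives. Of 780 list tests, 254 passed, and 57 with the estimated correlation. The array of vehicle rat 1003 of the male 6 h group held values displaced by 1 position over 42.4 percent of its probe sets. Each probe set count of that study is followed by that without this rat. This was planned for comparisons with its group and chosen after seeing the data for the others. List counts and gene values hold the rat unless stated.

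**Figure D1:**
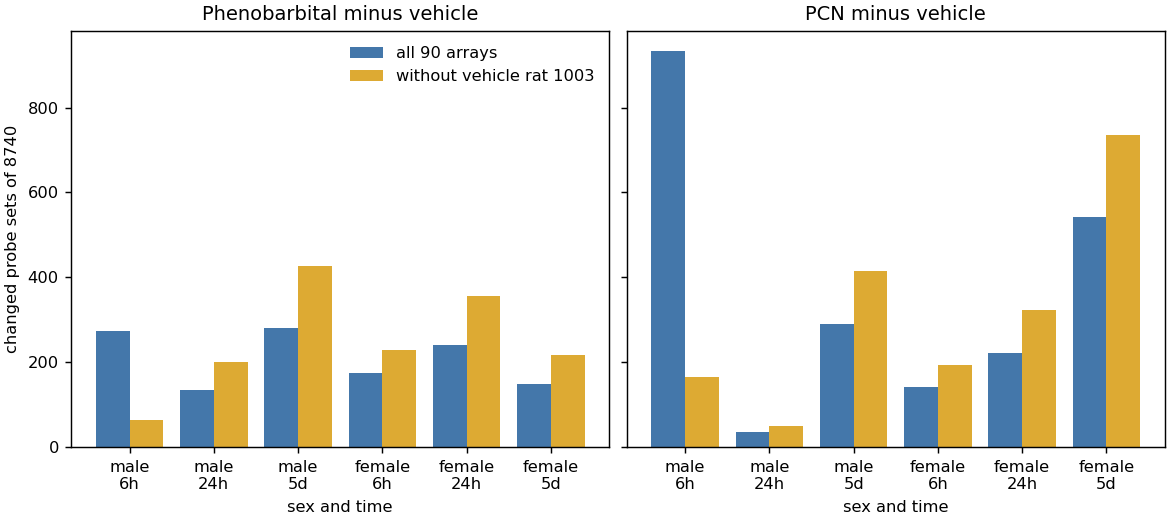
Bars give the number of changed probe sets of 8740 (vertical axis) by sex and time, for phenobarbital and for PCN against vehicle, with all 90 arrays and without vehicle rat 1003. Without that rat the male 6 h counts were 64 for phenobarbital and 166 for PCN, against 274 and 933 with it.

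What 5 doses of each inducer did to male liver was asked first (n = 5 per group). With phenobarbital the P450 Cyp2b2, the usual marker of CAR, rose by 3.29 ± 0.32, the glutathione transferase Gsta3 by 3.75 ± 0.34 and the exporter of conjugates Abcc3 by 2.54 ± 0.35. Cyp3a23-3a1, the usual marker of PXR, rose by 1.10 ± 0.17, and Alas1, the first enzyme of haem synthesis, by 1.69 ± 0.26. In the list of phase 1 enzymes induced through CAR or PXR, 7 of 12 members rose (7 adjusted over the list alone). Adjusted p was 5.3e-14 for this list (adjusted p = 8.4e-05 with an estimated correlation, range 2.9e-16 to 8.4e-05). For the NRF2 list 8 of 19 members rose (9 adjusted over the list alone). Adjusted p was 6.3e-12 for this list (adjusted p = 1.5e-04 with an estimated correlation, range 3.0e-15 to 1.5e-04). In all, phenobarbital changed 282 of 8740 probe sets (156 higher and 126 lower), 427 without rat 1003 and 114 with only the groups compared.

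After PCN in males for 5 days Gsta3 rose by 3.14 ± 0.34, Cyp2b2 by 2.48 ± 0.32, Alas1 by 2.02 ± 0.26, the hepatic uptake transporter Slco1a4 by 1.81 ± 0.21 and Cyp3a23-3a1 by 1.04 ± 0.17. The serine dehydratase Sds, which feeds amino acids into gluconeogenesis, changed by -4.94 ± 1.06. Of the proteasome list 15 of 26 members rose (18 adjusted over the list alone), with Psmb3 at 0.88 ± 0.15. Adjusted p was 1.9e-19 for this list (adjusted p = 0.0091 with an estimated correlation, range 1.9e-22 to 0.0091). Of the phase 1 list 7 of 12 members rose (8 adjusted over the list alone). Adjusted p was 4.0e-13 for this list (adjusted p = 1.5e-04 with an estimated correlation, range 7.7e-15 to 1.5e-04). Of the NRF2 list 10 of 19 members rose (10 adjusted over the list alone). Adjusted p was 4.5e-14 for this list (adjusted p = 3.5e-05 with an estimated correlation, range 2.3e-16 to 3.5e-05). Among genes of the urea cycle and amino acid breakdown, 6 of 28 members fell (6 adjusted over the list alone). Adjusted p was 3.2e-07 for this list (adjusted p = 0.17 with an estimated correlation, range 4.8e-09 to 0.17). PCN changed 291 of 8740 probe sets (187 higher and 104 lower), 414 without rat 1003 and 173 with only the groups compared. The higher calls were 64.3 percent, and 76.9 percent with median scaling.

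In females (n = 5 per group), 5 days of phenobarbital raised Cyp2b2 by 3.76 ± 0.32, Cyp3a2, a P450 with a male bias, by 2.70 ± 0.53 and Cyp3a23-3a1 by 1.24 ± 0.17. Genes of cholesterol synthesis rose together: 7 of 16 members rose (11 adjusted over the list alone), among them lanosterol synthase Lss at 1.35 ± 0.27. Adjusted p was 1.6e-17 for this list (adjusted p = 0.010 with an estimated correlation, range 8.8e-21 to 0.010). Phase 1 genes gave 5 of 12 members that rose (7 adjusted over the list alone) and genes of conjugation and transport 8 of 25 members that rose (11 adjusted over the list alone). Adjusted p was 1.3e-14 and 9.0e-17 for these tests in turn (adjusted p = 5.8e-05 and 3.0e-07 with an estimated correlation, ranges 1.9e-17 to 5.8e-05 and 7.0e-19 to 3.0e-07). In mitochondrial fatty acid oxidation 5 of 23 members fell (8 adjusted over the list alone), with the thiolase Acaa2 at -0.88 ± 0.16. Adjusted p was 5.4e-10 for this list (adjusted p = 0.054 with an estimated correlation, range 1.0e-13 to 0.054). Macrophage markers passed as a group only, while 0 of 9 members passed (0 adjusted over the list alone, median log2 change 0.40). Adjusted p was 4.8e-04 for this list (adjusted p = 0.11 with an estimated correlation, range 3.2e-04 to 0.11). The count was 150 of 8740 probe sets (94 higher and 56 lower), 217 without rat 1003, 84 with only the groups compared and 97 without vehicle female rat 1513.

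PCN given to females for 5 days raised Cyp3a18 by 3.66 ± 0.33, Cyp2b2 by 3.17 ± 0.32, the P450 reductase Por by 2.16 ± 0.26, the aldehyde reductase Akr7a3 by 2.77 ± 0.42 and Cyp3a23-3a1 by 1.35 ± 0.17. Genes with a male bias in rat liver also moved: 5 of 11 members rose (5 adjusted over the list alone), with the male P450 Cyp2c11 at 1.65 ± 0.24. Adjusted p was 1.2e-05 for this list (adjusted p = 0.010 with an estimated correlation, range 2.2e-07 to 0.010). Lower were Sds (-4.72 ± 1.06), the thyroxine carrier Serpina7 (-3.54 ± 0.57) and the fatty acid hydroxylase Cyp4a1, a target of PPARα (-2.07 ± 0.44). Of the NRF2 list 12 of 19 members rose (13 adjusted over the list alone). Adjusted p was 4.8e-16 for this list (adjusted p = 8.3e-06 with an estimated correlation, range 4.9e-20 to 8.3e-06). Conjugation genes gave 15 of 25 members that rose and 2 that fell (16 and 2 adjusted over the list alone) and phase 1 genes 7 of 12 members that rose (7 adjusted over the list alone). Adjusted p was 5.7e-16 and 2.0e-13 for these tests in turn (adjusted p = 3.0e-07 and 1.3e-04 with an estimated correlation, ranges 1.8e-18 to 3.0e-07 and 3.9e-15 to 1.3e-04). PCN changed 542 of 8740 probe sets (296 higher and 246 lower), and 736 without rat 1003.

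Both inducers were set against each other at the same dose and days (phenobarbital minus PCN, n = 5 each). In males the transporters Abcc3 and Slco1a4 differed by 1.81 ± 0.35 and -1.10 ± 0.21, and the sulfotransferase Sult2a1 by -1.38 ± 0.16. In females Sds differed by 5.84 ± 1.06, Cyp3a18 by -3.65 ± 0.33 and Alas1 by -1.16 ± 0.26. The difference in Cyp2b2 was 0.81 ± 0.32 in males (95 percent interval from 0.18 to 1.45) and 0.59 ± 0.32 in females (from -0.04 to 1.23), and did not pass in either sex. That in Cyp3a23-3a1 was 0.06 ± 0.17 (from -0.28 to 0.40) and -0.11 ± 0.17 (from -0.45 to 0.23), and did not pass either. Cholesterol synthesis was higher with phenobarbital in females, where 4 of 16 members rose (11 adjusted over the list alone). Adjusted p was 6.6e-09 for this list (adjusted p = 0.11 with an estimated correlation, range 2.3e-10 to 0.11). Macrophage markers differed in females too, where 3 of 9 members rose (4 adjusted over the list alone). Adjusted p was 2.6e-05 for this list (adjusted p = 0.054 with an estimated correlation, range 1.6e-05 to 0.054). The comparison gave 80 probe sets higher and 91 lower of 8740 in males, in all 267 without rat 1003, 35 with only the groups compared, 103 without phenobarbital male rat 4014 and 113 and 113 without PCN male rat 5012 and 5015 in turn. In females it gave 423 of 8740 probe sets (203 higher and 220 lower), 603 without rat 1003 and 272 with only the groups compared.

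Whether the 5-day effects differ between the sexes was tested as an interaction, female minus male. For PCN the effect on Cyp3a18 differed by 2.33 ± 0.46, that on the ribonuclease Rnase1 by 2.59 ± 0.58 and that on the glutathione transferase Gstm1 by 0.93 ± 0.21, and of the genes with a male bias 2 of 11 members rose (3 adjusted over the list alone). Adjusted p was 1.2e-05 for this list (adjusted p = 0.010 with an estimated correlation, range 5.6e-08 to 0.010). For phenobarbital the effect on the desaturase Scd2 differed by 2.43 ± 0.43, not past the threshold with a pseudocount of 1 (adjusted p = 0.11, range 3.8e-06 to 0.18) or with only the groups compared, that on the tubulin chaperone Tbce by -0.75 ± 0.16 and that on the kinase Grk4 by -2.58 ± 0.55. Tbce did not pass without vehicle male rat 1011 or 1015, vehicle female rat 1511, 1513 or 1514, phenobarbital male rat 4013, 4014 or 4015 or phenobarbital female rat 4512, 4513 or 4515 (-0.76 to -0.68, adjusted p = 0.050 to 0.13), and Grk4 did not without vehicle male rat 1012, 1013, 1014 or 1015, vehicle female rat 1511, 1514 or 1515, phenobarbital male rat 4012 or phenobarbital female rat 4513 (-2.58 to -2.39, adjusted p = 0.053 to 0.10). Macrophage markers beside them gave 0 of 9 members that passed (1 higher and 0 lower adjusted over the list alone, median log2 change 0.37). Adjusted p was 7.3e-04 for this list (adjusted p = 0.13 with an estimated correlation, range 1.8e-04 to 0.13). The effect on Cyp2b2 differed by 0.47 ± 0.45 with phenobarbital (95 percent interval from -0.43 to 1.37) and by 0.69 ± 0.45 with PCN (from -0.21 to 1.59), and passed for neither. The PCN effect differed for 37 of 8740 probe sets (18 higher and 19 lower), 53 without rat 1003 and 17 with only the groups compared. The phenobarbital effect differed for 5 of 8740 probe sets (3 higher and 2 lower), 9 without rat 1003, 3 with median scaling, 2 with the lowest 33.3 percent of probe sets left out, 0 with only the groups compared in limma, where 514 passed unadjusted, and 3 and 3 without vehicle male rat 1012 and 1015 in turn, 3 without vehicle female rat 1514 and 2 without phenobarbital female rat 4513.

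At 24 h after 1 dose of phenobarbital (n = 5 per group) Cyp2b2 rose by 3.76 ± 0.32 in males and 4.61 ± 0.32 in females, and Cyp3a23-3a1 by 1.26 ± 0.17 and 1.78 ± 0.17. The liver pyruvate kinase Pklr changed by -1.57 ± 0.27 in males and -1.37 ± 0.27 in females. Phase 1 genes gave 7 of 12 members that rose (7 adjusted over the list alone) in males and 6 of 12 members that rose (8 adjusted over the list alone) in females. Adjusted p was 9.1e-24 and 1.7e-19 for these tests in turn (adjusted p = 3.0e-07 and 2.9e-06 with an estimated correlation, ranges 5.2e-28 to 3.0e-07 and 1.6e-23 to 2.9e-06). The proteasome list moved in both sexes, where 5 of 26 members rose (14 adjusted over the list alone) in males and 15 of 26 members rose (18 adjusted over the list alone) in females. Adjusted p was 5.2e-13 and 2.0e-29 for these tests in turn (adjusted p = 0.050 and 5.6e-04 with an estimated correlation, ranges 2.6e-15 to 0.050 and 2.8e-33 to 5.6e-04). Stellate cell markers moved beside it in females, as 1 of 16 members fell (1 adjusted over the list alone). Adjusted p was 0.031 for this list (adjusted p = 0.35 with an estimated correlation, range 0.015 to 0.35). Genes of glucose metabolism gave 3 of 17 members that fell (4 adjusted over the list alone) in males. Adjusted p was 1.3e-06 for this list (adjusted p = 0.0034 with an estimated correlation, range 1.5e-07 to 0.0034). In males phenobarbital changed 134 of 8740 probe sets (80 higher and 54 lower), 201 without rat 1003, 83 without vehicle male rat 1006 and 82 without phenobarbital male rat 4009. In females it changed 240 of 8740 probe sets (154 higher and 86 lower), 356 without rat 1003, 155 with only the groups compared and 145 without phenobarbital female rat 4506, and 64.2 percent were higher, 77.0 percent with median scaling.

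PCN at 24 h raised Cyp3a23-3a1 by 1.48 ± 0.17 in males and 2.18 ± 0.17 in females, and Cyp2b2 by 1.70 ± 0.32 and 2.63 ± 0.32 (n = 5 per group). Genes of the cell cycle rose in both sexes, with 3 of 19 members that rose (6 adjusted over the list alone) in males and 5 of 19 members that rose (9 adjusted over the list alone) in females. Adjusted p was 1.8e-09 and 3.8e-07 for these tests in turn (adjusted p = 0.0018 and 0.010 with an estimated correlation, ranges 3.0e-14 to 0.0018 and 2.2e-07 to 0.010). Among them were the microtubule regulator Stmn1 at 1.25 ± 0.24 in males and 1.36 ± 0.24 in females and the mitotic kinase Cdk1 at 1.58 ± 0.25 and 0.98 ± 0.25. Of the phase 1 list 4 of 12 members rose (6 adjusted over the list alone) in males and 5 of 12 members rose (8 adjusted over the list alone) in females. Adjusted p was 7.3e-11 and 8.2e-16 for these tests in turn (adjusted p = 7.0e-04 and 3.0e-05 with an estimated correlation, ranges 1.3e-11 to 7.0e-04 and 2.8e-20 to 3.0e-05). In males PCN changed 37 of 8740 probe sets (30 higher and 7 lower), 50 without rat 1003 and 8 with only the groups compared, with 81.1 percent higher, 91.2 percent with median scaling. In females it changed 223 of 8740 probe sets (134 higher and 89 lower), 323 without rat 1003.

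The earliest time, 6 h, was read first in females (n = 5 per group). Phenobarbital raised Cyp2b2 by 3.33 ± 0.32, the kinase Pdk4, which turns off glucose oxidation, 18.3-fold (SE 0.59 on the log2 scale) and Igfbp1 by 5.32 ± 0.91. Heat shock genes were lower, as 4 of 10 members fell (6 adjusted over the list alone), with the chaperone Hsph1 at -2.60 ± 0.41 and the HSP90 partner Fkbp4 at -2.11 ± 0.26. Adjusted p was 2.0e-14 for this list (adjusted p = 3.6e-04 with an estimated correlation, range 2.0e-14 to 3.6e-04). Phase 1 genes gave 2 of 12 members that rose (2 adjusted over the list alone). Adjusted p was 1.7e-06 for this list (adjusted p = 0.019 with an estimated correlation, range 1.7e-06 to 0.019). PCN raised Cyp2b2 by 2.08 ± 0.32, Cyp3a23-3a1 by 1.94 ± 0.17 and Alas1 by 1.48 ± 0.26, with 4 of 12 members that rose (5 adjusted over the list alone) in the phase 1 list. Adjusted p was 1.6e-12 for this list (adjusted p = 2.2e-04 with an estimated correlation, range 7.3e-13 to 2.2e-04). Phenobarbital changed 175 of 8740 probe sets (94 higher and 81 lower), 228 without rat 1003, 27 with only the groups compared and 287 without phenobarbital female rat 4505. PCN changed 142 of 8740 probe sets (101 higher and 41 lower), 195 without rat 1003 and 89 with only the groups compared.

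In males at 6 h the values without rat 1003 are given (n = 4 vehicle and 5 treated rats). Phenobarbital then raised Cyp2b2 by 3.84 ± 0.31, Alas1 by 1.60 ± 0.27 and Por by 1.03 ± 0.27. PCN raised Cyp2b2 by 2.82 ± 0.31, Alas1 by 1.91 ± 0.27, Por by 1.33 ± 0.27, Cyp3a23-3a1 by 1.31 ± 0.18 and Gclc by 1.25 ± 0.27. With all arrays Cyp2b2 rose by 4.23 ± 0.32 and 3.21 ± 0.32, and 6 of 12 members rose (10 adjusted over the list alone) in the phase 1 list with phenobarbital, 6 of 12 members rose (8 adjusted over the list alone) with PCN. Adjusted p was 3.9e-10 and 1.3e-09 for these tests in turn (adjusted p = 0.0012 and 0.0018 with an estimated correlation, ranges 1.8e-10 to 0.0012 and 1.0e-09 to 0.0018). Phenobarbital changed 274 of 8740 probe sets (189 higher and 85 lower) with all arrays and 64 without rat 1003, and PCN 933 of 8740 probe sets (437 higher and 496 lower) with all arrays and 166 without it. With another rat left out the phenobarbital count was 1264, 1333, 1249 and 1235 without vehicle male rat 1001, 1002, 1004 and 1005 in turn and 146, 138, 122 and 125 without phenobarbital male rat 4001, 4002, 4003 and 4004 in turn. The PCN count was 1412 and 1474 without vehicle male rat 1001 and 1002 in turn and 385, 277, 255, 297 and 279 without PCN male rat 5001, 5002, 5003, 5004 and 5005 in turn. With only the groups compared the counts were 1 for phenobarbital and 3 for PCN. The phenobarbital count was 788 with a pseudocount of 64, and the PCN count 552 with the lowest 33.3 percent of probe sets left out. The direction turned too: with phenobarbital 69.0 percent of calls were higher with all arrays, 37.3 percent with a pseudocount of 64 and 44.2 to 45.9 percent without vehicle rat 1001, 1002, 1004 or 1005. With PCN 46.8 percent were higher with all arrays, 50.4 with median scaling, 53.3 with a pseudocount of 1, 71.0 with the lowest 33.3 percent left out and 70.4 to 74.9 without a PCN rat. Without rat 1003 84.4 and 69.9 percent were higher.

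Vehicle rats gave the sex difference (female minus male, n = 15 each over 3 times). The male P450s Cyp3a2 and Cyp2c13 differed by -6.91 ± 0.31 and -6.22 ± 0.28. The female P450 Cyp2c12 gave 2.79 ± 0.30, with rat 1003 at 4.00 (its group 8.20 to 9.27). Of genes with a male bias 1 of 11 members rose and 7 fell (1 and 7 adjusted over the list alone). Of those with a female bias 7 of 10 members rose and 1 fell (7 and 1 adjusted over the list alone). Adjusted p was 2.1e-16 and 5.8e-05 for these tests in turn (adjusted p = 1.0e-06 and 0.010 with an estimated correlation, ranges 1.2e-33 to 1.0e-06 and 2.1e-10 to 0.010). Of the ribosome list 19 of 26 members rose (21 adjusted over the list alone). Adjusted p was 1.3e-09 for this list (adjusted p = 0.053 with an estimated correlation, range 2.0e-10 to 0.053). Cyp2b2 differed by -0.22 ± 0.18 (95 percent interval from -0.59 to 0.14) and did not pass. The sexes differed in 1281 of 8740 probe sets (737 higher and 544 lower), 1338 without rat 1003.

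D3T served as the reference for NRF2 (n = 4 per group). The glutathione transferases Gsta3 and Gstp1 rose by 5.21 ± 0.21 and 4.80 ± 0.32, Akr7a3 by 3.37 ± 0.13 and the quinone reductase Nqo1 by 2.72 ± 0.18. Of the NRF2 list 9 of 19 members rose (10 adjusted over the list alone). Adjusted p was 1.7e-08 for this list (adjusted p = 0.043 with an estimated correlation, range 9.9e-09 to 0.043). Cholesterol synthesis was lower, as 7 of 16 members fell (9 adjusted over the list alone), with Sqle at -2.90 ± 0.36 and Idi1 at -2.65 ± 0.21. Adjusted p was 2.7e-05 for this list (adjusted p = 0.25 with an estimated correlation, range 2.9e-06 to 0.25). The phase 1 list gave 3 of 12 members that rose and 2 that fell (4 and 3 adjusted over the list alone), and its mean and test differed in sign (-0.03, tested higher). Adjusted p was 0.98 for this list (adjusted p = 1.0 with an estimated correlation, range 0.50 to 1.0). Control arrays were 3.02 times as bright as D3T arrays as deposited. D3T changed 1091 of 8740 probe sets (466 higher and 625 lower), 701 without control rat 3 and 351 with the rat number as a block, where Sqle did not pass.

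Wy-14643 served as the reference for PPARα at 1, 3 and 7 days (n = 3 per group). The acyl-CoA thioesterase Acot1, a sensitive target of PPARα, rose by 7.84 ± 0.38, 7.86 ± 0.38 and 8.39 ± 0.38 at these times and Cyp4a1 by 2.67 ± 0.13, 2.78 ± 0.13 and 2.76 ± 0.13. In mitochondrial fatty acid oxidation 17 of 24 members rose (22 adjusted over the list alone) at 1 day and 21 of 24 members rose (21 adjusted over the list alone) at 7 days, and in peroxisomal oxidation 13 of 18 members rose (14 adjusted over the list alone, with 1 lower) at 7 days. Adjusted p was 5.0e-25, 3.8e-27 and 2.2e-14 for these tests in turn (adjusted p = 0.014, 0.010 and 0.025 with an estimated correlation, ranges 3.4e-25 to 0.014, 2.8e-27 to 0.010 and 1.7e-14 to 0.025). The PPARα list gave 20 of 27 members that rose (20 adjusted over the list alone) at 7 days. Adjusted p was 8.8e-17 for this list (adjusted p = 0.027 with an estimated correlation, range 5.3e-17 to 0.027). In the cell cycle list 19 of 33 members rose (26 adjusted over the list alone) at 1 day, 20 of 33 members rose (21 adjusted over the list alone) at 3 days and 0 of 33 members passed (0 adjusted over the list alone, median log2 change 0.21) at 7 days. Adjusted p was 3.6e-14, 5.0e-13 and 0.17 for these tests in turn (adjusted p = 0.11, 0.13 and 0.82 with an estimated correlation, ranges 2.7e-14 to 0.11, 2.3e-13 to 0.13 and 0.13 to 0.82). Complement and coagulation genes gave 13 of 19 members that fell (15 adjusted over the list alone) at 7 days. Adjusted p was 3.4e-11 for this list (adjusted p = 0.059 with an estimated correlation, range 1.7e-12 to 0.059). The phase 1 list gave 3 of 12 members that rose (3 adjusted over the list alone, with 2 lower) at 1 day, when its median was -0.12 and its mean 0.31. Adjusted p was 0.76 for this list (adjusted p = 0.90 with an estimated correlation, range 0.23 to 0.96). It gave 3 of 12 members that rose and 3 that fell (4 and 3 adjusted over the list alone) at 3 days and 2 of 12 members that rose and 2 that fell (4 and 3 adjusted over the list alone) at 7 days. Adjusted p was 0.63 and 0.81 for these tests in turn (adjusted p = 0.86 and 0.92 with an estimated correlation, ranges 0.22 to 0.86 and 0.37 to 0.92).

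Markers of other cell types moved beside these groups in the Wy-14643 rats. The log2 difference between the 3' and 5' GAPDH control probe sets, a sign of RNA quality, lay between 0.50 and 0.74 in the 9 treated rats and between 0.78 and 0.94 in the 9 controls. It differed by -0.14, -0.32 and -0.30 at 1, 3 and 7 days, each with p = 0.1 in an exact permutation test (two-sided, adjusted p = 0.73), the smallest that 3 against 3 rats allow. Mean intensity was 446 to 559 in treated and 361 to 426 in control rats at 1 day and 529 to 609 and 314 to 446 at 3 days (each exact p = 0.1, adjusted p = 0.72), and overlapped at 7 days. Macrophage markers gave 0 of 14 members that passed (0 adjusted over the list alone, median log2 change -0.53) at 3 days and 4 of 14 members that fell (10 adjusted over the list alone) at 7 days, stellate markers 3 of 18 members that fell (3 adjusted over the list alone) at 7 days and blood markers 1 of 6 members that fell (3 adjusted over the list alone) at 3 days. Adjusted p was 0.0077, 0.0011, 0.013 and 0.031 for these tests in turn (adjusted p = 0.48, 0.39, 0.39 and 0.35 with an estimated correlation, ranges 0.0034 to 0.48, 1.4e-04 to 0.39, 0.013 to 0.39 and 0.018 to 0.35). Between 7 days and 1 day the effect on the mitotic kinase Aurka differed by -3.24 ± 0.47, that on the asparagine synthetase Asns by 3.07 ± 0.43 and that on the apolipoprotein gene Apoa4 by -5.43 ± 0.79, and of the cell cycle list 3 of 33 members fell (10 adjusted over the list alone). Adjusted p was 1.8e-10 for this list (adjusted p = 0.19 with an estimated correlation, range 1.7e-10 to 0.19). Beside it macrophage markers gave 0 of 14 members that passed (0 higher and 9 lower adjusted over the list alone, median log2 change -1.11), blood markers 0 of 6 members that passed (0 higher and 2 lower adjusted over the list alone, median log2 change -0.68) and stellate markers 0 of 18 members that passed (0 adjusted over the list alone, median log2 change -0.37). Adjusted p was 1.4e-04, 0.029 and 0.034 for these tests in turn (adjusted p = 0.35, 0.35 and 0.46 with an estimated correlation, ranges 6.6e-06 to 0.35, 0.028 to 0.35 and 0.032 to 0.46). The counts were 1815 of 15866 probe sets (936 higher and 879 lower) at 1 day, 1710 of 15866 probe sets (879 higher and 831 lower) at 3 days and 2076 of 15866 probe sets (1045 higher and 1031 lower) at 7 days, and the effect differed between 7 days and 1 day for 300 of 15866 probe sets (169 higher and 131 lower). The 1-day count was 1204 without control rat 22 and 1182 without Wy-14643 rat 03. At 3 days it was 1110 without control rat 29 and 896 and 1026 without Wy-14643 rat 07 and 08 in turn and 724 with only the groups compared, and at 7 days 968 with only the groups compared. The count of the difference was 192 without control rat 22 and 196 without Wy-14643 rat 03. At 1 day 51.6 percent were higher, 67.1 percent with median scaling, and in the difference 56.3 percent, 41.9 percent with median scaling.

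PFOA against vehicle (n = 3 each) asked whether CAR and PXR targets respond to a carboxylate. The CAR marker Cyp2b2 was not read on this array. Acot1 rose by 8.26 ± 0.44, the pantetheinase Vnn1 by 4.03 ± 0.08, the carnitine transferase Cpt1b 18.4-fold (SE 0.32 on the log2 scale), the peroxisome division gene Pex11a by 3.76 ± 0.13 and Cyp4a1 by 1.64 ± 0.27. Of the PPARα list 13 of 29 members rose (20 adjusted over the list alone, with 2 lower), of peroxisomal oxidation 12 of 19 members rose and 1 fell (14 and 1 adjusted over the list alone) and of mitochondrial oxidation 13 of 24 members rose (16 adjusted over the list alone, with 1 lower). Adjusted p was 1.8e-10, 5.6e-10 and 1.9e-12 for these tests in turn (adjusted p = 0.010, 0.029 and 0.083 with an estimated correlation, ranges 1.7e-10 to 0.010, 2.7e-10 to 0.029 and 1.6e-12 to 0.083). Of the phase 1 list 6 of 12 members rose and 2 fell (6 and 2 adjusted over the list alone). Adjusted p was 0.013 for this list (adjusted p = 0.22 with an estimated correlation, range 7.3e-04 to 0.23). With the other normalization it was 0.23. Examples were Por at 3.74 ± 0.51, Aldh1a1 at 2.53 ± 0.18, Alas1 at 2.44 ± 0.48 and the carboxylesterase Ces2c at 3.38 ± 0.44. Cyp3a23-3a1 rose by 0.41 ± 0.07, and both members that fell, Cyp2c7 at -0.79 ± 0.18 and Cyp3a18 at -0.26 ± 0.05, were singled out after their values were seen. Cyp3a23-3a1 did not pass with median scaling (0.13, adjusted p = 0.83), with the lowest 33.3 percent left out (0.41, adjusted p = 0.16) or without vehicle rat R95434, R95435 or R95436 or PFOA rat R95470 or R95472 (0.36 to 0.42, adjusted p = 0.055 to 0.077). Nor did Alas1 without vehicle rat R95435 or PFOA rat R95470, R95471 or R95472 (2.41 to 2.68, adjusted p = 0.075 to 0.11), Cyp2c7 without vehicle rat R95434, R95435 or R95436 or PFOA rat R95471 or R95472 (-0.82 to -0.65, adjusted p = 0.098 to 0.14) and Cyp4a1 with any 1 of the 6 rats left out (1.54 to 1.68, adjusted p = 0.054 to 0.075). Heat shock genes gave 7 of 12 members that rose (10 adjusted over the list alone) and complement and coagulation 11 of 26 members that fell (21 adjusted over the list alone). Adjusted p was 1.6e-07 and 3.7e-12 for these tests in turn (adjusted p = 0.13 and 0.13 with an estimated correlation, ranges 1.4e-07 to 0.13 and 4.3e-13 to 0.13). Beside these, macrophage markers gave 1 of 15 members that fell (1 adjusted over the list alone) and endothelial markers 2 of 13 members that fell (4 adjusted over the list alone). Adjusted p was 0.0020 and 0.031 for these tests in turn (adjusted p = 0.46 and 0.35 with an estimated correlation, ranges 0.0015 to 0.46 and 0.029 to 0.35). PFOA changed 1888 of 31042 probe sets (1003 higher and 885 lower), 1183 with median scaling and 1161, 697 and 772 without vehicle rat R95434, R95435 and R95436 in turn and 1174 and 860 without PFOA rat R95471 and R95472 in turn.

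**Figure D2:**
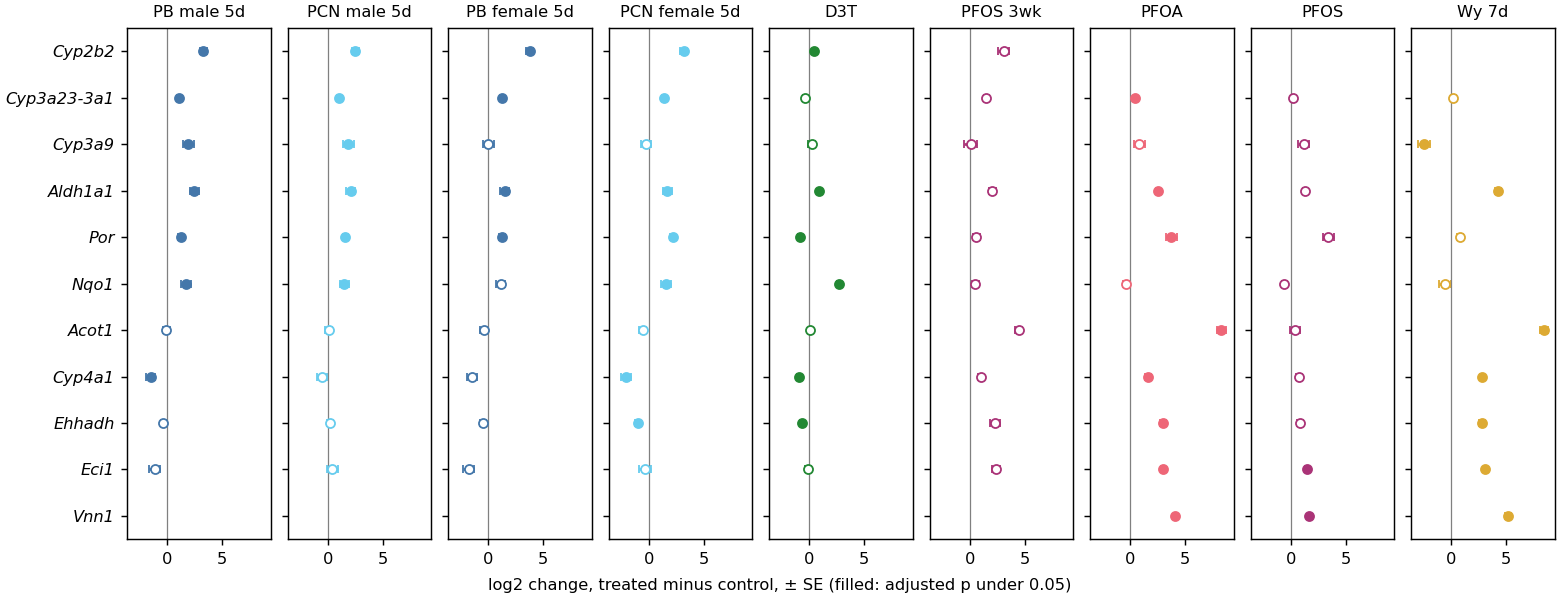
Log2 change ± SE (horizontal axis) of 11 genes in 9 comparisons, treated minus control, filled where the adjusted p passed, with genes absent from an array left blank. Cyp2b2 changed by 3.29 with phenobarbital in males at 5 days and by 0.45 with D3T, and Acot1 by 8.39 with Wy-14643 at 7 days and by 8.26 with PFOA.

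PFOS against the same vehicle (n = 3 each) put that question to a sulfonate. The transcription factor genes Dbp and Bmal1 of the circadian clock changed by 4.16 ± 0.13 and -3.19 ± 0.10. Of mitochondrial oxidation 4 of 24 members rose (7 adjusted over the list alone) with the carnitine transferase Cpt2 at 1.38 ± 0.17, and of peroxisomal oxidation 1 of 19 members rose (6 adjusted over the list alone). Adjusted p was 0.0028 and 0.0033 for these tests in turn (adjusted p = 0.40 and 0.21 with an estimated correlation, ranges 1.2e-04 to 0.40 and 8.6e-05 to 0.21). Cpt2 in PFOS rats did not pass without vehicle rat R95434, R95435 or R95436 or PFOS rat R95479, R95480 or R95481 (1.25 to 1.49, adjusted p = 0.072 to 0.12). Vnn1 rose by 1.63 ± 0.08. For the phase 1 list 0 of 12 members passed (5 higher and 0 lower adjusted over the list alone, median log2 change 0.20). Adjusted p was 0.0045 for this list (adjusted p = 0.17 with an estimated correlation, range 0.0012 to 0.17). Of these 5 the largest value was that of Por at 3.41 ± 0.51 (adjusted p = 0.056, not passed), which lay between 11.54 and 11.61 in PFOS and between 7.39 and 9.46 in vehicle rats. The other 4 of them were Aldh1a1 at 1.27 ± 0.18, Ces2c at 1.71 ± 0.44, Cyp2c6v1 at 0.19 ± 0.04 and Cyp3a23-3a1, named here after their values were seen. Acot1 stood at 0.37 ± 0.44 (95 percent interval from -0.68 to 1.42), Cyp3a23-3a1 at 0.22 ± 0.07 (from 0.05 to 0.38) and Cyp4a1 at 0.79 ± 0.27 (from 0.13 to 1.44), and none of these passed. Complement and coagulation genes gave 0 of 26 members that passed (0 adjusted over the list alone, median log2 change -0.19), and macrophage markers beside them 1 of 15 members that fell (1 adjusted over the list alone). Adjusted p was 1.4e-04 and 0.017 for these tests in turn (adjusted p = 0.39 and 0.57 with an estimated correlation, ranges 1.3e-04 to 0.94 and 0.016 to 0.57). PFOS changed 143 of 31042 probe sets (88 higher and 55 lower), 75 with only the groups compared and 84, 44 and 52 without vehicle rat R95434, R95435 and R95436 in turn and 66 and 46 without PFOS rat R95480 and R95481 in turn. The higher calls were 61.5 percent, 77.8 percent with median scaling, 47.7 percent without vehicle rat R95435 and 46.2 percent without R95436.

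**Figure D3:**
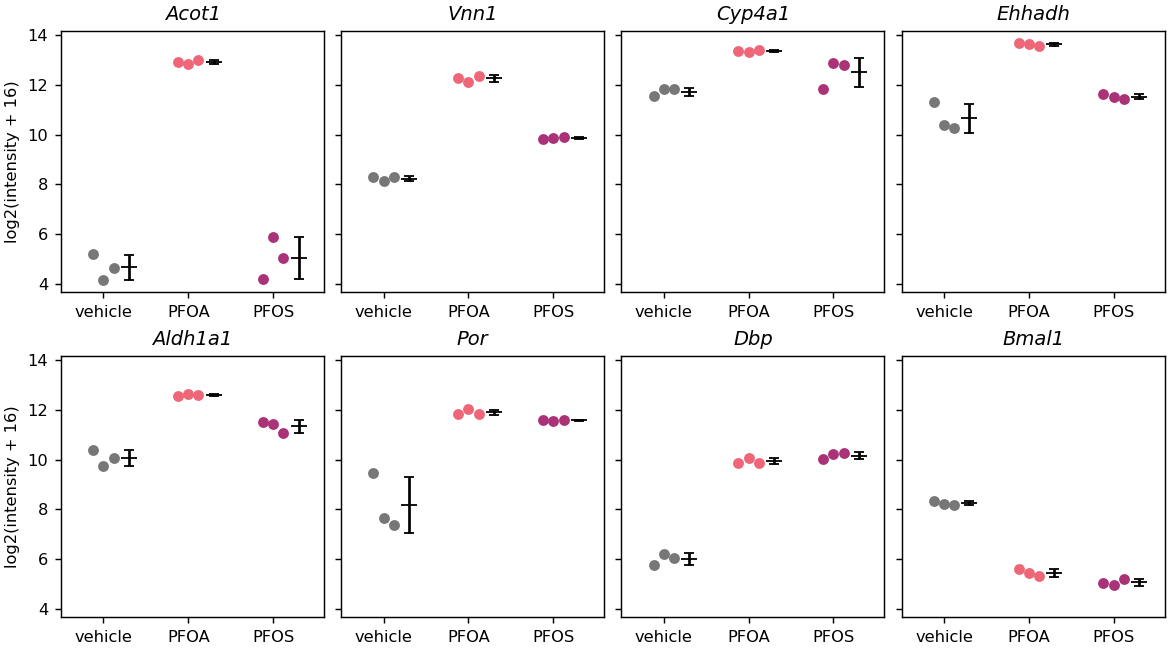
Points give log2(intensity + 16) of 8 genes in each of the 9 rats given vehicle, PFOA or PFOS, with the group mean ± SD beside them. Acot1 was at 12.84 or more in the PFOA rats and at 5.20 or less in the vehicle rats.

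PFOA and PFOS were then compared directly, a carboxylate at 20 against a sulfonate at 10 mg/kg/day, so that the doses differ. Acot1 was higher with PFOA by 7.89 ± 0.44, Cpt1b by 4.08 ± 0.32 and Pex11a by 2.83 ± 0.13, while Idi1 differed by -2.89 ± 0.25. Of the PPARα list 9 of 29 members rose (19 adjusted over the list alone), of peroxisomal oxidation 9 of 19 members rose (13 adjusted over the list alone, with 1 lower), of mitochondrial oxidation 8 of 24 members rose (14 adjusted over the list alone, with 1 lower) and of cholesterol synthesis 4 of 23 members fell (13 adjusted over the list alone). Adjusted p was 2.9e-12, 1.4e-11, 6.1e-13 and 2.3e-08 for these tests in turn (adjusted p = 0.0079, 0.025, 0.078 and 0.11 with an estimated correlation, ranges 2.5e-12 to 0.0079, 1.1e-11 to 0.025, 5.4e-13 to 0.078 and 6.8e-09 to 0.11). Beside these, endothelial markers gave 0 of 13 members that passed (0 higher and 3 lower adjusted over the list alone, median log2 change -0.33) and stellate markers 1 of 18 members that fell (2 adjusted over the list alone). Adjusted p was 0.028 and 0.056 for these tests in turn (adjusted p = 0.35 and 0.42 with an estimated correlation, ranges 0.013 to 0.35 and 0.030 to 0.42). For the phase 1 list 1 of 12 members rose (2 adjusted over the list alone, with 1 lower). Adjusted p was 0.25 for this list (adjusted p = 0.54 with an estimated correlation, range 0.14 to 0.59). Not passed were Cyp3a23-3a1 at 0.20 ± 0.07 (95 percent interval from 0.03 to 0.36), Alas1 at 1.30 ± 0.48 (from 0.16 to 2.44) and Cyp4a1 at 0.86 ± 0.27 (from 0.20 to 1.51). The compounds differed in 411 of 31042 probe sets (219 higher and 192 lower), 178 with only the groups compared and 219 and 222 without PFOA rat R95471 and R95472 in turn and 144 and 148 without PFOS rat R95480 and R95481 in turn. Of these 53.3 percent were higher with PFOA, 28.8 percent with median scaling.

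After 3 weeks of PFOS in females, at another dose (n = 2 per group), 0 of 8740 probe sets passed in limma, and 421 passed unadjusted. The values of Acot1 and Cyp2b2 were 4.45 ± 0.32 (adjusted p = 0.39) and 3.06 ± 0.48 (adjusted p = 0.75), and that of Cyp3a23-3a1 was 1.51 ± 0.20 (95 percent interval from 0.78 to 2.25). As a group the phase 1 list was higher, with 0 of 12 members that passed (0 adjusted over the list alone, median log2 change 0.59). Adjusted p was 6.6e-07 for this list (adjusted p = 0.30 with an estimated correlation, range 6.0e-07 to 0.30). So were mitochondrial oxidation, with 0 of 23 members that passed (3 higher and 0 lower adjusted over the list alone, median log2 change 0.38), and peroxisomal oxidation, with 0 of 11 members that passed (0 adjusted over the list alone, median log2 change 0.59). Adjusted p was 3.2e-08 and 1.7e-06 for these tests in turn (adjusted p = 0.50 and 0.50 with an estimated correlation, ranges 3.0e-08 to 0.50 and 2.4e-08 to 0.50). Macrophage markers beside them gave 0 of 9 members that passed (0 adjusted over the list alone, median log2 change -0.39). Adjusted p was 0.045 for this list (adjusted p = 0.58 with an estimated correlation, range 0.017 to 0.58). The count was 17 with a pseudocount of 1 and 25 with the lowest 33.3 percent of probe sets left out.

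The genes that each reference compound changed at least 2-fold were then tested as signatures in the perfluoroalkyl acid rats, with phenobarbital and PCN taken from 5 days in the same sex. In the PFOA rats the rising Wy-14643 genes were higher, 192 of 211 matched genes with a median of 1.28 (adjusted p = 5.2e-36, adjusted p = 9.2e-05 with an estimated correlation, range 5.2e-36 to 9.2e-05). The 32 rising phenobarbital genes had a median of 0.36 (adjusted p = 0.22, range 0.020 to 0.64) and the 28 rising PCN genes one of 0.39 (adjusted p = 0.061, range 2.9e-04 to 0.63). Without the genes that Wy-14643 also changed, these medians were -0.11 (adjusted p = 0.96) and -0.09 (adjusted p = 0.80). In the PFOS rats the rising Wy-14643 genes had a median of 0.29 (adjusted p = 5.7e-07, adjusted p = 0.0071 with an estimated correlation, range 5.1e-07 to 0.0071), the phenobarbital genes one of 0.21 (adjusted p = 0.26) and the PCN genes one of 0.22 (adjusted p = 0.20). After 3 weeks of PFOS in females 24 of 29 rising phenobarbital genes were higher (median 0.58, adjusted p = 4.8e-07, adjusted p = 0.38 with an estimated correlation, range 6.1e-08 to 0.38). So were 59 of 74 PCN genes (median 0.35, adjusted p = 1.4e-10, adjusted p = 0.38 with an estimated correlation, range 3.0e-11 to 0.38) and 81 of 111 Wy-14643 genes (median 0.28, adjusted p = 6.4e-10, adjusted p = 0.47 with an estimated correlation, range 2.1e-12 to 0.47). Without the genes that Wy-14643 changed, 18 of 21 phenobarbital genes and 39 of 49 PCN genes were higher (adjusted p = 2.5e-05 and adjusted p = 9.2e-08, each adjusted p = 0.38 with an estimated correlation, ranges 1.5e-06 to 0.38 and 3.7e-08 to 0.38). The rising D3T genes had adjusted p = 0.081 here (65 matched genes), 0.80 in PFOA and 0.12 in PFOS rats (62 in each). Of the genes that a reference lowered, the 180 Wy-14643 genes were lower as a group in PFOA rats (median -0.92, adjusted p = 6.6e-18, adjusted p = 0.012 with an estimated correlation, range 6.6e-18 to 0.012) and in PFOS rats (median -0.17, adjusted p = 0.0058, adjusted p = 0.38 with an estimated correlation, range 0.0043 to 0.38). After 3 weeks of PFOS 88 of 119 D3T genes were lower (median -0.21, adjusted p = 0.0014, adjusted p = 0.80 with an estimated correlation, range 0.0013 to 0.80). So were 21 of 29 exclusive PCN genes (median -0.32, adjusted p = 0.040, adjusted p = 0.84 with an estimated correlation, range 0.016 to 0.84). The other falling signatures did not pass, except the Wy-14643 genes that phenobarbital or PCN did not change, in PFOA and PFOS rats (adjusted p = 4.5e-17 and 0.0073, adjusted p = 0.012 and 0.38 with an estimated correlation).

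**Figure D4:**
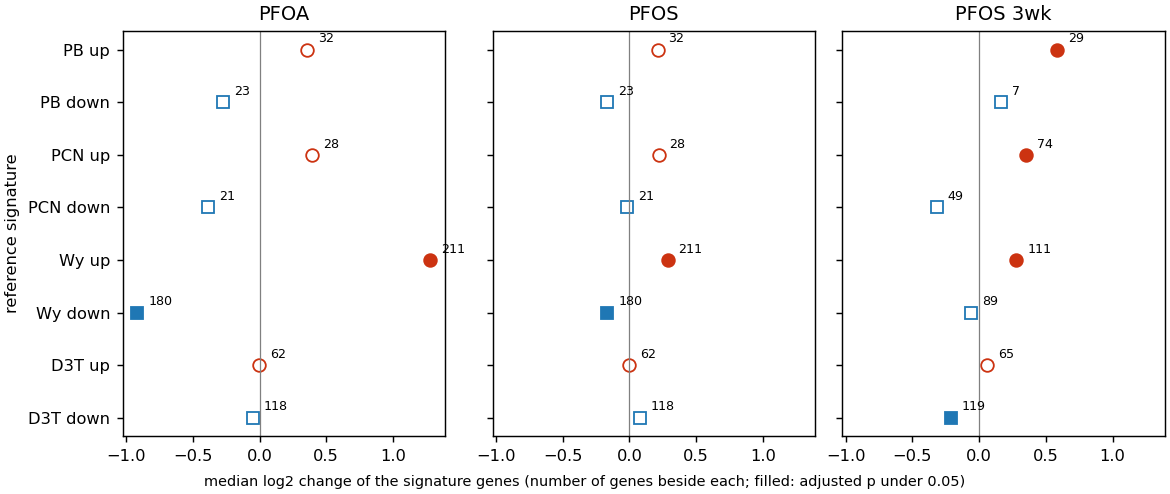
Points give the median log2 change (horizontal axis) of the genes that each reference compound raised (circles) or lowered (squares) in the PFOA, PFOS and 3-week PFOS rats, with the number of genes beside each and filled where the adjusted p passed. The genes raised by Wy-14643 had a median of 1.28 in the PFOA rats and 0.29 in the PFOS rats.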

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

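The test of displaced values and the splits of the 3 differences between effects were chosen only after the result was seen. In each group of 4 or 5 rats the most extreme rat was compared with the rest for array measures and key genes. Of 280 such tests, 34 rats' values stood apart, 5 of them those of vehicle rat 1003 of the male 6 h group. In 47 tests a rat was at the floor of 4.00, which can fix the outcome, so the 16 found there were not set against chance. In the other 233 tests 18 stood apart, where chance gives about 1 in 20 groups. In that rat the mean correlation with the rest of its group was 0.623 (others 0.879 to 0.884), the log2 difference between the 3' and 5' GAPDH control probe sets -1.44 (others 0.45 to 0.53), Cyp4a1 4.00 (others 8.50 to 9.14), Acot1 5.79 (others 4.00 to 4.22) and Cyp2c12 4.00 (others 8.20 to 9.27).

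Over the first 3731 of 8799 probe sets, 42.4 percent, the array of rat 1003 had a correlation across genes of 0.205 with the mean of the other 4 rats. With these values moved back by 1 position it was 0.976, against 0.972 over the other probe sets, so a displacement by 1 position may account for the rat's distance from its group. The value of 0.972 argues against a wrong label as the only cause, since that would change both parts. A label from a close group stays open, since moved back the rat's mean correlation with phenobarbital males at 6 h differed from that with its own group by -0.00060 (0.961 against 0.962), too little to part these groups. No biological explanation was tested.

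Other single rats stood apart from their group by the same measure, and no explanation was tested for them. The mean correlation with the rest of the group was 0.952 in PCN male 5-day rat 5013 (others 0.961 to 0.964). The GAPDH 3' to 5' log2 difference was 2.53 in phenobarbital male 5-day rat 4013 (others 0.40 to 0.64). It was 2.01 in PCN male 5-day rat 5013 (others 0.21 to 0.63), of the same place. It was 0.66 in D3T rat 3 (others 0.46 to 0.49). The mean intensity was 184 in vehicle female 24 h rat 1506 (others 322 to 374). Cyp4a1 read 9.72 in phenobarbital female 6 h rat 4505 (others 10.94 to 11.03) and 9.36 in PCN male 6 h rat 5003 (others 8.42 to 8.49). In the rats that follow Acot1 was apart from others at 4.00 to 4.63. It read 4.34 in vehicle male 24 h rat 1010, 4.45, 4.31 and 6.77 in vehicle female rats 1504 (6 h), 1509 (24 h) and 1514 (5 days), 4.44 and 4.26 in phenobarbital male rats 4005 (6 h) and 4006 (24 h), 5.62 in phenobarbital female 24 h rat 4506, 4.42 and 5.19 in PCN male rats 5006 (24 h) and 5013 (5 days) and 4.47 in D3T rat 1. Cyp1a1 read 4.45 in vehicle male 6 h rat 1001 (others 4.00), 4.71 in vehicle male 5-day rat 1013 (others 4.00) and 4.78 in vehicle female 5-day rat 1515 (others 4.26 to 4.35). Cyp2c12 read 7.95 in phenobarbital male 24 h rat 4010 (others 8.85 to 9.16) and 10.21 in phenobarbital female 24 h rat 4506 (others 10.71 to 10.81). Cyp7a1 read 4.84 in vehicle male 24 h rat 1007 (others 7.13 to 7.57) and 7.40 in PCN male 5-day rat 5014 (others 4.00). Cyp2c11 read 7.19 in vehicle female 6 h rat 1502 (others 7.91 to 8.18) and 7.13 in vehicle female 24 h rat 1507 (others 8.13 to 8.35). Cyp2b2 read 12.70 in phenobarbital male 6 h rat 4003 (others 12.53 to 12.57). Cyp3a9 read 9.63 in phenobarbital male 24 h rat 4008 (others 8.79 to 8.97). Nqo1 read 7.47 in PCN female 6 h rat 5505 (others 8.55 to 8.96). These gene values are on the log2 scale with a floor of 4.00.

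A further 3 results were differences between effects that passed an interaction test. The phenobarbital effect at 5 days differed between females and males at 5 probe sets, the PCN effect at 37, and the Wy-14643 effect between 7 days and 1 day at 300. Splits that moved treatment labels within each sex or time gave as many in 6, 4 and 6 of 100 splits, with highest other counts 54, 4.62 and 3.14 times the real ones. A split calling several times the real count points to a structure of the samples, since moving labels within a sex or time turns a treatment effect into a difference between effects. That scheme was therefore replaced after its outcome was seen. In the second, sex or time means and the treatment effect common to both were taken off each gene before the labels were moved, and 1 of 100 splits each, the real one, gave as many, with highest other counts of 2, 9 and 4. For PCN both shares were under 0.05, for Wy-14643 the second alone, which leaves chance open. For phenobarbital it was left open too, since the 5 probe sets came to 0 with only the groups compared (limma, 514 unadjusted) and 2 without female rat 4513.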

How the results depend on the processing

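Tests with the values of vehicle rat 1003 moved back, those without it, except counts and genes of comparisons that hold its group, and those of the place of the rat number were chosen after the results were seen, and the others were planned. Of the counts under an alternative, 390 stayed within 1.5 times and 84 did not. Named genes kept their direction and side of the threshold in 17356 alternatives, passed no longer in 2419 (1661 of them with an array left out), passed newly in 33 and turned in 1. Gene lists did so in 4196, 356, 122 and 6, and signatures in 141, 12, 11 and 0. Leaving a rat out of the 3-week PFOS study left an arm of 1 rat, assumed to vary like the other arm, and gave 0 probe sets in limma with each rat left out, with 548 to 1023 at an unadjusted p under 0.05. Where a value moved, the cause was not tested, except that a fit of fewer arrays holds less information on the spread. Signal over background limits the genes at the floor of 4.00, whose changes are understated.

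With only the groups compared the counts were 1, 114, 27, 155 and 84 for phenobarbital in males at 6 h and 5 days and females at 6 h, 24 h and 5 days. They were 3, 8, 173 and 89 for PCN in males at 6 h, 24 h and 5 days and females at 6 h. Phenobarbital minus PCN gave 35 in males and 272 in females, the sex differences of the phenobarbital and PCN effects 0 (limma, 514 unadjusted) and 17, PFOS 75, PFOA minus PFOS 178, and Wy-14643 724 at 3 and 968 at 7 days.

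Other settings moved phenobarbital in males at 6 h to 788 (pseudocount 64), PCN in males at 6 h to 552 (lowest 33.3 percent left out) and the sex difference of the phenobarbital effect to 3 (median scaling) and 2 (lowest 33.3 percent left out). PFOA moved to 1183 with median scaling, and 3-week PFOS to 17 with a pseudocount of 1 and 25 with the lowest 33.3 percent left out. For D3T the replicate block gave 351, and 57 named gene results no longer passed while 40 kept their side, although the numbers do not pair the rats (r of same-number deviations across genes from -0.205 to 0.266). In the phenobarbital and PCN study, without rat 1003, rats of the same sex and time whose numbers had the same place in their groups deviated together in part. The r of deviations across genes had a mean of 0.138 (from -0.076 to 0.496) in 88 such pairs, 53 of them over 0.1, against -0.034 in other pairs, and 36 of 60 treated rats correlated best with the vehicle rat of their place (2 had none). The place held 82.1 percent of the variance within groups of the GAPDH 3' to 5' difference in females (permutation p = 1e-05, the smallest possible here, adjusted p = 4e-05) and 69.9 percent in males (permutation p = 2.7e-04, adjusted p = 5.4e-04), and 52.7 and 64.5 percent of that of log2 mean intensity (permutation p = 0.034 and 0.0046, adjusted p = 0.034 and 0.0061). Place thus held part of the spread, left out of main fit and splits. A replicate block by place gave 849 for phenobarbital in males at 6 h and left the other 17 counts of that and the 3-week PFOS study within 1.5 times. Of named gene results 600 kept their side of the threshold, 9 no longer passed and 2 newly passed. In the 3-week PFOS study r was 0.380 in both pairs, too few to decide, and the block gave 0 probe sets (limma, 757 unadjusted). With rat 1003 moved back the counts were 83 and 158 for phenobarbital and PCN in males at 6 h, 262 for phenobarbital minus PCN in males and 9 for the sex difference of the phenobarbital effect. Without rat 1003 they were 64, 166, 267 and 9, and 427 for phenobarbital in males at 5 days.

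Leaving out each array in turn gave 64 to 1333, 82 to 201 and 205 to 427 for phenobarbital in males at 6 h, 24 h and 5 days and 120 to 287, 145 to 356 and 97 to 217 in females. For PCN in males at 6 h the range was 166 to 1474, for phenobarbital minus PCN in males 103 to 267 and for the sex difference of the phenobarbital effect 2 to 9. It was 701 to 982 for D3T, 697 to 1608 for PFOA, 44 to 128 for PFOS, 144 to 598 for PFOA minus PFOS, 1182 to 1422 and 896 to 1764 for Wy-14643 at 1 and 3 days and 192 to 377 for 7 days minus 1 day.

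With an estimated correlation 57 of 254 list calls and 6 of 16 signature calls passed. Turned in direction, with their p then, were complement and coagulation in males at 6 h of phenobarbital (0.031 without rat 1003), mitochondrial oxidation in males at 6 h of PCN (0.0040 without rat 1003 and 0.042 with it moved back), urea and amino acids there (0.71 and 0.45) and acute phase in D3T (0.79 with the other normalization). Over their alternatives the adjusted p of these 4 list tests lay from 0.031 to 0.74, from 0.0040 to 0.87, from 0.0060 to 0.71 and from 2.2e-06 to 0.79. Fabp1 in D3T was -0.37 and turned to 0.57 with median scaling.

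Signature tests that changed sides had these adjusted p. In PFOA rats the top 100 genes gave 0.0038 for lower phenobarbital genes, 0.015 for those exclusive of Wy-14643, 0.00029 for higher PCN genes and 4.2e-06 for lower ones, the earlier time 0.020 for higher phenobarbital genes, and references without rat 1003 gave 0.029 for higher PCN genes. In PFOS rats the top 100 gave 0.011 and 0.035 for higher and lower PCN genes, and the estimated correlation 0.38 for lower Wy-14643 genes in both versions. In 3-week PFOS rats the estimated correlation gave 0.38 for higher phenobarbital and PCN genes in both versions, 0.47 for higher Wy-14643 genes in both, 0.84 for lower exclusive PCN genes and 0.80 for lower D3T genes. There the earlier time gave 0.78 for lower exclusive PCN genes and 0.078 for higher exclusive Wy-14643 genes, the top 100 gave 0.049 for lower exclusive phenobarbital genes and 0.039 for higher D3T genes, and references without rat 1003 gave 0.00033 for the genes that phenobarbital lowers, which were higher here (median 0.77), against that signature. Over their alternatives the adjusted p in PFOA rats lay from 0.020 to 0.64 (higher phenobarbital genes), from 0.0038 to 0.47 (lower), from 0.015 to 0.78 (lower exclusive), from 2.9e-04 to 0.63 (higher PCN) and from 4.2e-06 to 0.47 (lower). In PFOS rats it lay from 0.011 to 0.84 and from 0.035 to 0.84 for higher and lower PCN genes and from 0.0043 to 0.38 and from 0.0034 to 0.38 for lower Wy-14643 genes, all and exclusive. In 3-week PFOS rats it lay from 6.1e-08 to 0.38 and from 1.5e-06 to 0.38 for higher phenobarbital genes, from 3.3e-04 to 0.90 for those it lowers, with the lowest of these p on the higher side, from 0.049 to 0.90 for the exclusive ones, from 3.0e-11 to 0.38 and from 3.7e-08 to 0.38 for higher PCN genes, from 0.016 to 0.84 for lower exclusive ones, from 2.1e-12 to 0.47 and from 1.9e-05 to 0.47 for higher Wy-14643 genes, and from 0.039 to 0.80 and from 0.0013 to 0.80 for higher and lower D3T genes.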

Other observations

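The patterns tested in this part were noticed in the same data, and each test was fixed before its own result was seen, except the splits without rat 1003, which were chosen only after the result was seen. Further gene groups moved in the rats given Wy-14643, beside a lower GAPDH 3' to 5' difference (0.50 to 0.74 against 0.78 to 0.94). At 1 day, of the acute phase list 11 of 26 members fell (15 adjusted over the list alone), among them the protease inhibitors A2m at -1.34 ± 0.27 and Serpina3n at -0.65 ± 0.10 and the lectin Mbl1 at -0.72 ± 0.12. Adjusted p was 3.2e-07 for this list (adjusted p = 0.037 with an estimated correlation, range 8.7e-10 to 0.037). Of the ER stress list 6 of 22 members fell (9 adjusted over the list alone), with the disulfide isomerases Pdia3 at -0.67 ± 0.09 and Pdia6 at -0.57 ± 0.08. Adjusted p was 5.4e-04 for this list (adjusted p = 0.33 with an estimated correlation, range 3.1e-04 to 0.33). At 3 days, of the lipogenesis list 7 of 19 members rose and 2 fell (8 and 2 adjusted over the list alone), with the desaturase Fads2 at 2.20 ± 0.23 and malic enzyme Me1 at 3.71 ± 0.50. Adjusted p was 1.6e-04 for this list (adjusted p = 0.35 with an estimated correlation, range 1.3e-04 to 0.35). Lymphocyte markers had a lower effect at 7 days than at 1 day as a group, while 0 of 21 members passed (0 adjusted over the list alone, median log2 change -0.59), with Cd74 at -1.41 ± 0.68. Adjusted p was 0.021 for this list (adjusted p = 0.12 with an estimated correlation, range 0.0093 to 0.12).

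In females Mdm2, the p53 target that holds p53 down, rose by 2.55 ± 0.20 after 5 days of PCN, where of the p53 damage list 1 of 5 members rose (1 adjusted over the list alone). Adjusted p was 0.020 for this list (adjusted p = 0.062 with an estimated correlation, range 4.2e-08 to 0.068). At 6 h of phenobarbital Cyp1a1, the usual marker of AHR, changed by -0.89 ± 0.19, close to the floor, and of the AHR list 1 of 5 members fell (1 adjusted over the list alone). Adjusted p was 0.014 for this list (adjusted p = 0.10 with an estimated correlation, range 0.0059 to 0.10). In the PFOA rats, of the bile acid list 1 of 18 members rose and 5 fell (1 and 7 adjusted over the list alone), with the bile acid carrier Slco1a1 at -1.39 ± 0.15. Adjusted p was 0.0044 for this list (adjusted p = 0.32 with an estimated correlation, range 7.1e-04 to 0.32). In the PFOS rats, of the nuclear receptor list 1 of 29 members fell (2 adjusted over the list alone, with 1 higher), the member being Ppard at -1.21 ± 0.15, which did not pass with any 1 of the 6 rats left out. Adjusted p was 0.021 for this list (adjusted p = 0.19 with an estimated correlation, range 0.020 to 0.19). Bile duct markers did not pass as a group there, where 0 of 10 members passed (0 adjusted over the list alone, median log2 change 0.33), with Tspan8 at 1.35 ± 0.65. Adjusted p was 0.074 for this list (adjusted p = 0.54 with an estimated correlation, range 0.069 to 0.54).

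In the PFOS and PFOA rats some clock genes stood out. Bmal1 changed by -3.19 and -2.82 in turn, Npas2 by -3.97 and -4.13 and Dbp by 4.16 and 3.94, and the fall of Npas2 is understated where treated rats were at the floor. Dbp lay between 10.02 and 10.27 in PFOS, 9.88 and 10.07 in PFOA and 5.75 and 6.20 in vehicle rats. Per2 changed by 2.74 with PFOA and stood at 2.62 with PFOS (adjusted p = 0.090). Of the clock list 1 of 15 members rose and 2 fell (6 and 3 adjusted over the list alone) with PFOS. Adjusted p was 0.16 for this list (adjusted p = 0.53 with an estimated correlation, range 0.053 to 0.53, and 0.17 to 0.76 with PFOA). The study's dimmest array, of PFOS rat R95479 (mean intensity 245), does not account for this. At least 96.2 percent of the change of Bmal1, Npas2 and Dbp was kept without it. Livers taken at another hour may account for it. The median change of the Per, Nr1d, Tef and Hlf genes exceeded that of Clock and Cry1 by 1.54 in PFOS rats. This decides nothing, as Clock at -1.37 and Cry1 at 0.72 went opposite ways. A shift of the clock by the compounds gives the same pattern. Labels give no hour to part them, and a link to phase 1 changes was not tested.

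The D3T changes came with a difference in array brightness, the control arrays being 3.02 times as bright. Within groups of the 90-array study the slope of each probe set on brightness predicted a median of 10.7 percent of the D3T changes, 7.49 percent for NRF2 genes and 0.705 percent for cholesterol synthesis, and across probe sets, which are not independent replicates, Spearman's rho was 0.118. As the slopes came from arrays of mean 159 to 453 and D3T arrays lay at 92.2 to 116, brightness was left open. RNA integrity is argued against, as the GAPDH 3' to 5' log2 difference differed by 0.062 between the groups. The effect of D3T itself remains among the explanations, as a hypothesis.

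Labels were also moved between groups. For phenobarbital in males at 6 h 3 of 100 splits gave as many as the real 274 probe sets, the highest other 882, several times the real count, which points to a structure of the samples, the displaced array of rat 1003. For PCN there the real split alone, 1 of 100, gave as many, with 933 and a highest other of 908. As both hold the displaced array, these splits were not used to exclude chance. Without rat 1003, 2 of 100 splits gave as many as the real 64 for phenobarbital (highest other 84). For PCN 1 of 100, the real one, gave as many as 166 (highest other 101), so both shares were under 0.05. In females at 6 h of phenobarbital 2 of 100 gave as many as 175 (highest other 220). In each other group comparison of that study the real split alone, 1 of 100, gave as many. These shares are under 0.05, but splits without place leave chance open. With phenobarbital the real count and the highest other were 134 and 27 at 24 h and 282 and 110 at 5 days in males, and 240 and 81, and 150 and 52 in females. With PCN they were 37 and 20 at 24 h and 291 and 85 at 5 days in males, and 142 and 50, 223 and 30, and 542 and 251 in females. Phenobarbital minus PCN gave 80 higher and 91 lower against a highest other of 100 in all in males, and 423 and 154 in females. The vehicle sexes gave 1281 and 70. For D3T 1 of 35 splits, the real one, gave as many (1091 and 17), a share under 0.05. The 10 splits of 3 against 3 rats are too few for a share under 0.05. There the real count and the highest other were 1888 and 16 for PFOA, 143 and 6 for PFOS, 411 and 4 for PFOA minus PFOS, and 1815 and 2, 1710 and 2, and 2076 and 3 for Wy-14643 at 1, 3 and 7 days.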
